A study of Schistosoma mansoni with 42 samples.

How the data were processed

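Adult and juvenile blood flukes (Schistosoma mansoni) were exposed in culture to praziquantel, the drug used to treat schistosomiasis, and their RNA was measured on 42 two-colour Agilent oligonucleotide arrays. Worms recovered from mice 28 days after infection were mixed-sex pools, and worms recovered at 42 days were males or females. Doses were 0, 1 and 10 µg/mL. The sample labels give the exposures as 60 min or overnight, and the series' design text gives 1 and 20 h, the times used here. The labels describe 14 groups of 3 biological replicates named A, B and C, in 5 sets that each have their own unexposed control.

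On every array the worm RNA carried Cy5 and a common reference RNA carried Cy3, per the labels, so all ratios run in one direction and a dye effect does not cancel within a group. The reference was mainly RNA of unexposed 42 day worms of both sexes with small additions from exposed and juvenile worms. The deposited table holds the processed red and green intensity of each probe on a linear scale, per the file headers, and the method behind the processing is not given in the sources used here. The deposited series matrix holds log2 ratios, which differed from log2 of the red over the green intensity by at most 5.0e-09. The tables list 24332 probes with 0 missing values, and all columns could be matched to a sample. No detection flags were used here.

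Probe identifiers consist of a prefix and a number, with 12166 prefixes of 2 probes each. The files do not pair the identifiers with gene names, and 0 probes matched any identifier in the supplied table of 13257 genes. The 20 gene lists chosen before the data were examined (drug transporters, calcium channels and pumps, muscle, eggshell and others) could therefore not be tested, and probes are given by identifier only. On each array the probe pairs of one prefix had log ratios correlated at 0.863 to 0.942 across 5532 prefixes with both probes of above-median signal, against -0.031 to 0.003 after shuffling.

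The measured value was log2(Cy5/Cy3) per probe. Array medians ranged from -0.13 to 0.14, a spread of 0.27 that exceeded the limit of 0.1 set in the plan, so each array was centred on its median. One linear model with a mean for each of the 14 groups was fitted to all 42 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, leaving 28 residual degrees of freedom. A probe was called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p given for a probe comes from this limma fit unless another is named. There were 20 planned comparisons, of which 9 set an exposed group against its control, 4 set the doses against each other and 6 tested a difference between responses, and the remaining one compared unexposed females with males.

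The rule for named genes, also set before the data were examined, took annotated probes that were called and whose 3 values in the one group did not overlap the 3 in the other, in order of the size of their change in each direction, with 1 probe per gene. Chance alone gives such separation to 10% of unchanged probes. Annotation being absent, the same order was applied to identifiers with 1 probe per prefix, and at most 2 are named each way in a comparison, a limit set after the data were seen. Probes followed across all groups were chosen after their values were seen. A signal under 2 times the array's 5th percentile (5.88 to 25.5 units in Cy5) counts as under the floor. Where the dimmer group was under it on any array, the change is given as a bound after raising those values to the floor. This bound holds for median-centred ratios in the fit on all arrays, and some other settings gave smaller changes. It is not firm where Cy3 signals were also under the floor. No change is given where both groups were under the floor on all arrays. Probes under the floor made up 11.1% to 30.8% of an array.

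Because the reference RNA was the same everywhere, the Cy3 signal was used to look for technical batches. After quantile normalization of the above-median probes, the first 2 principal components (54.0% and 16.4% of variance) placed the arrays in 3 separate clusters of 11, 15 and 16 arrays. Arrays lay at most 3.52 from their cluster's centre and the centres at least 21.6 apart. The clusters are called reference batches 1, 2 and 3. The labels give no batch.

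Other settings chosen before the data were examined were the replicate letter as a block within each set, a fit on only the groups compared, quantile normalization between arrays, uncentred ratios, the series matrix, omission of the 25% of probes with the lowest mean signal, array weights, the mean of both probes of a prefix, and omission of each array in turn. Default array weights did not converge and gave 1 array a weight of 45.7, so limma's gene-by-gene weights (0.093 to 2.85) were used. Those chosen after seeing the data were the reference batches as a block, contrasts within a batch (a lone array in a group being assumed to vary like the others), centring on the above-median probes, Cy5 alone after quantile normalization, removal on each array of the loess trend of the log ratio with mean probe signal, and omission of 1 outlying male array. Replicates were described as biological by the labels, so p-values measure the spread between those samples, and 3 arrays per group limit the precision.

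The fit was tested on simulated data before use. For each of the 9 comparisons with a control, 200 of 24332 probes were given a known change on noise of the observed size. This noise was drawn independently for each probe and array. It held no reference batches, no outlying array and no deviations shared across probes, so the rates below do not cover these. Of changes of 2 on the log2 scale, 81.8% to 95.5% were recovered, of changes of 1, 41.8% to 61.2%, and of changes of 0.5, 5.97% to 13.4%, with 2 to 7 false calls per comparison.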

Results

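The 42 arrays measured transcripts of 28 day mixed-sex worms after 1 or 20 h at 0, 1 or 10 µg/mL praziquantel, of 42 day males after 1 h at the same doses and after 20 h at 0 or 1 µg/mL, and of 42 day females after 20 h at 0, 1 or 10 µg/mL, with 3 arrays per group. Median Cy5 signals ranged from 88.9 to 228 units and median Cy3 signals from 96.5 to 219. The 28 day worms exposed for 20 h had the lowest mean Cy5 medians, at 99.3 ± 10.3 units for 1 µg/mL and 110.0 ± 8.30 for 10 µg/mL, against 121 ± 22.2 in their controls (SD, n = 3). Reference batch 1 held 11 arrays of 42 day worms after 20 h, batch 2 held 15 arrays of 28 day worms, and batch 3 held all 9 arrays of males after 1 h and 7 others.

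**Figure D1:**
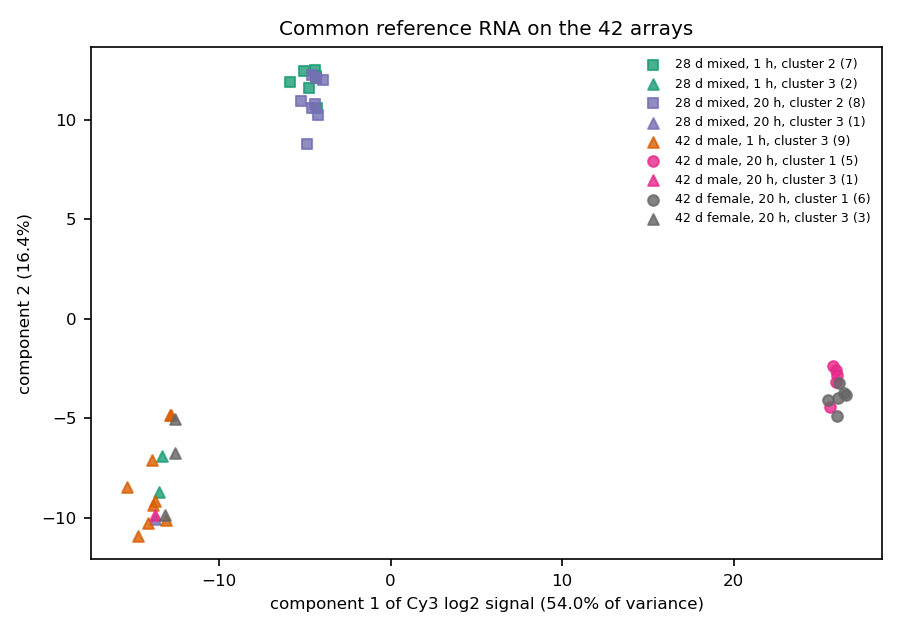
Scores of the 42 arrays on the first 2 principal components of the Cy3 log2 signal of the common reference RNA, with colour for the set of worms and symbol for the cluster (circle 1, square 2, triangle 3). The arrays form 3 groups of 11, 15 and 16, and several sets of worms fall into more than 1 of them.

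The widest change was in 28 day worms after 20 h. At 1 µg/mL, 1597 probes were higher and 4720 lower than in the controls, and at 10 µg/mL 960 were higher and 3450 lower. Of these, 2432 changed at least 2-fold at 1 µg/mL and 1430 at 10 µg/mL. TC14903_223 was under the signal floor on 2 of 3 control arrays, so only a bound is given, at least 143-fold higher at 1 µg/mL (adjusted p = 1.4e-07) and at least 75.9-fold at 10 µg/mL (adjusted p = 1.5e-06). The other probe of this prefix, measured on all arrays, rose by 5.65 and 4.62 on the log2 scale. TC14903_223 stood at 6.16 ± 0.33 in unexposed 42 day females, beside 5.03 ± 0.25 in 28 day worms at 1 µg/mL (log2 ratio, SD, n = 3), and was under the floor on 1 of 3 arrays of unexposed males after 20 h.

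TC16575_157 rose by 4.70 ± 0.38 at 1 µg/mL (SE, adjusted p = 9.8e-10) and 3.86 ± 0.38 at 10 µg/mL (adjusted p = 8.4e-08), and the other probe of its prefix rose by 2.15 at 1 µg/mL. TC9673_430 was at least 16.9-fold lower at 1 µg/mL (adjusted p = 3.1e-05), under the floor on 2 of 3 exposed arrays, while the other probe of its prefix did not pass (adjusted p = 0.20). With 10 µg/mL it was under the floor on all exposed arrays and at least 18.7-fold lower. TC18080_1142 was at least 11.1-fold lower at 1 µg/mL (adjusted p = 1.2e-05), under the floor on 2 of 3 exposed arrays, and the other probe of its prefix at least 7.78-fold (adjusted p = 0.0016), under it on 1 of 3. In unexposed females TC9673_430 and TC18080_1142 were under the floor on 2 and 1 of 3 arrays. Over 13 other settings their smallest log2 changes at 1 µg/mL were -3.91 and -3.36, less than the bounds above.

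**Figure D2:**
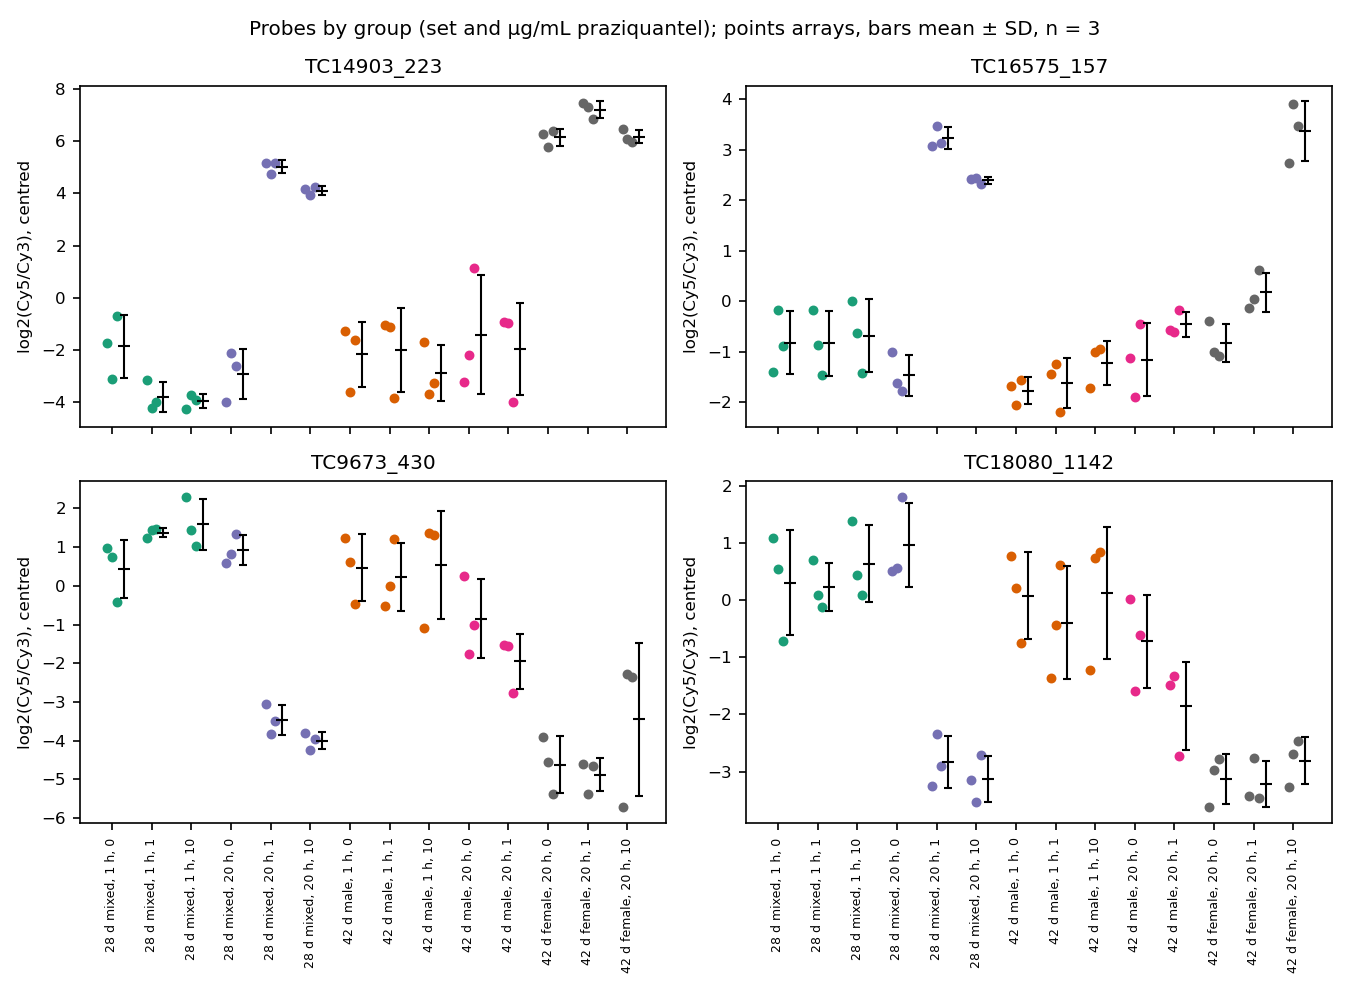
Centred log2(Cy5/Cy3) of 4 probes on each array (points) in the 14 groups, with mean ± SD (n = 3) as bars. TC14903_223 and TC16575_157 stand high in the 28 day worms exposed for 20 h, and TC9673_430 and TC18080_1142 stand low there; the first is also high and the last pair also low in females, and TC16575_157 is high in females at 10 µg/mL. Low values of the other 3 probes lie partly under the signal floor and are not exact.

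The balance of rises and falls in this set depended on centring. At the lower dose 25.3% of calls were rises with median centring, 42.4% without centring and 50.7% with centring on the above-median probes, and at 10 µg/mL the shares were 21.8%, 47.4% and 53.0%. The median of all probes moved by 0.13 to 0.19 between these scalings. Under all 3 scalings, 1597 rises and 2945 falls were called at 1 µg/mL, and 960 rises and 1830 falls at 10 µg/mL. These equal the rises with median centring and the falls with centring on above-median probes, so they do not settle the balance. With the trend with brightness removed on each array there were 2622 rises and 2612 falls at 1 µg/mL and 1732 and 1714 at 10 µg/mL, 5234 and 3446 in all. With the reference batches as a block there were 5927 and 4173 calls, and within batch 2, 4948 and 3216. Omission of 10 µg/mL replicate A left 2905 calls at that dose, array weights raised the counts to 9477 and 8391, and the mean of both probes of a prefix gave 3538 and 2502.

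**Figure D3:**
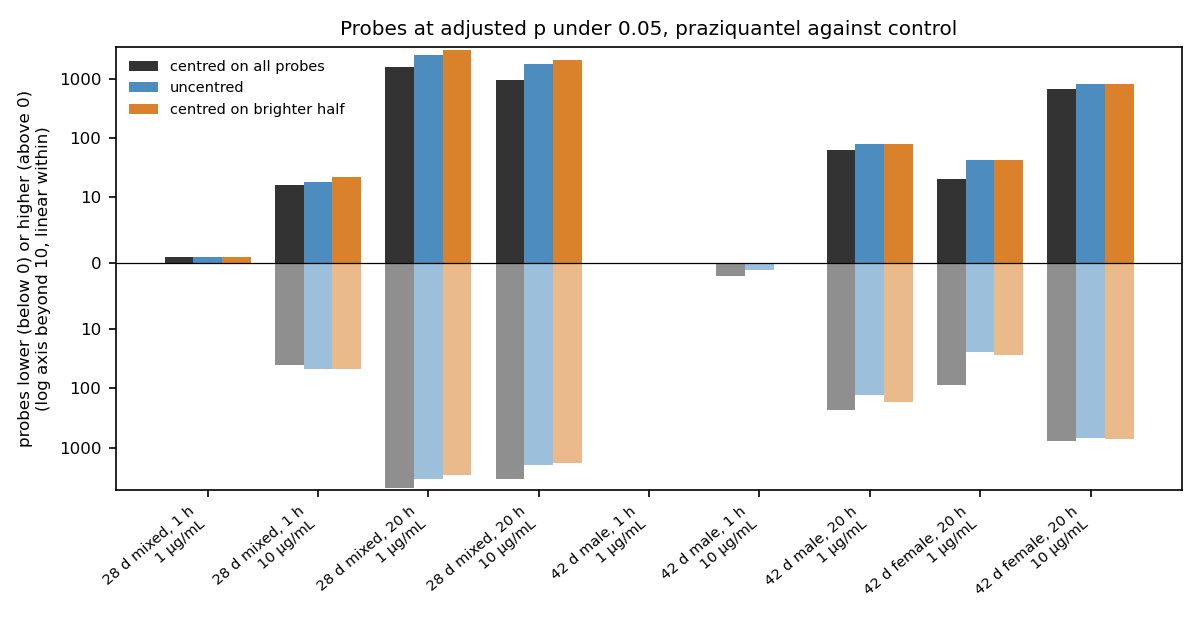
Number of probes higher (above 0) and lower (below 0) than control at adjusted p under 0.05 in the 9 comparisons, under 3 ways of centring; the axis is linear up to 10 and logarithmic beyond. The 28 day worms after 20 h have the most calls, 6317 and 4410 with median centring.

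The doses gave similar profiles in this set. Fold changes at 1 and 10 µg/mL correlated at 0.93 across 12166 above-median probes, against 0.51 from simulated unchanged groups with shared controls. Their covariance was 0.262 against 0.026 simulated. The simulation drew each probe independently and held no batches, so it gives no spread for deviations shared across probes. The lists shared 795 rises and 2943 falls, where independent lists would share 63.0 and 669, and part of the excess may come from the shared controls. Between doses 2 probes differed by direct test, TC17617_361, at least 16.9-fold higher at 10 µg/mL (adjusted p = 0.018) with Cy3 signals under the floor on all 6 arrays, and TC18843_712, lower by a log2 change of -1.37 ± 0.23 (adjusted p = 0.018). Their calls were lost under 1 and 2 of 13 other settings and with 4 and 5 of 6 omissions of an array. The count was 0 in a fit on these 6 arrays alone, 11 without 1 µg/mL replicate A, 1 without 10 µg/mL replicate C, and 0 without 1 µg/mL replicate B or C or 10 µg/mL replicate A.

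After 1 h, 28 day worms showed few changes. A single probe was called at 1 µg/mL, TC14645_450, higher by 1.02 ± 0.17 (adjusted p = 0.021), and the other probe of its prefix differed by 0.94 without passing (adjusted p = 0.080). This call was lost under 4 of 14 other settings, among them the replicate block (adjusted p = 0.076), with adjusted p from 1.1e-04 to 0.76 over all of them. The 1 probe called with the replicate block was another one, which was lower. At 10 µg/mL 16 probes were higher and 41 lower. TC10266_146, under the floor on 1 of 3 exposed arrays, was at least 17.5-fold lower (adjusted p = 0.0014) and the other probe of its prefix, under it on 2 of 3, at least 12.7-fold, and TC7164_897 fell by 3.71 ± 0.49 (adjusted p = 3.4e-04). TC16057_191, under the floor on 2 of 3 control arrays and in Cy3 on all 6, was at least 3.82-fold higher (adjusted p = 8.5e-04), and the other probe of its prefix did not pass (adjusted p = 0.34). TC16535_621 rose by 1.86 ± 0.31 (adjusted p = 0.0019). The call of TC16535_621 was lost under 2 of 13 other settings, that of TC7164_897 under 1 of 13 and that of TC16057_191 under 1 of 12.

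The count at 10 µg/mL fell to 37 with the reference batches as a block and to 22 within batch 2, and came to 30, 89 and 21 without control replicate A, B or C and to 27 without 10 µg/mL replicate C. A fit on these 6 arrays alone called 1, and such a fit at 1 µg/mL called 0. The single call at 1 µg/mL became 8 with that block, 6 within batch 2 and 38 within batch 3, where 1 exposed and 1 control array were compared; it became 0 without control A or 1 µg/mL replicate B or C, 4 without control B or C, and 17 without 1 µg/mL replicate A. The doses gave 0 calls against each other, with 1025 probes at an unadjusted p under 0.05, 1217 expected by chance, 2 calls within batch 2 and 8, 4 and 7 without 10 µg/mL replicate B, 10 µg/mL replicate A or 1 µg/mL replicate A.

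In 42 day males after 1 h almost no probe passed. For 1 µg/mL limma called 0 probes, with 952 at an unadjusted p under 0.05, 4 called from Cy5 alone, and 15, 2 and 2 called without control C, exposed B or exposed C. At 10 µg/mL 2 probes were called, both lower. TC18800_491 fell by 1.70 ± 0.29 (adjusted p = 0.036) and lost its call under 5 of 12 other settings. TC12631_436 was under the floor on all 3 exposed and 1 of 3 control arrays and in Cy3 on 5 of 6. With the exposed values raised to the floor the fall was 1.16-fold (adjusted p = 0.036), no firm bound because the dim control value stayed as measured. TC12631_436 lost its call under 8 of 11 other settings, and the other probe of its prefix was higher by 0.57 without passing (adjusted p = 0.55). All 9 arrays of this set lay in reference batch 3, so a contrast within it kept the estimates and changed only the residual variance and its degrees of freedom. That fit called 0 probes at either dose, which is no check on the batches. At 10 µg/mL the replicate block and a fit on only the groups compared also gave 0. Replicate A at 10 µg/mL stood apart, with a log-ratio SD of 1.06 and a mean Cy5 correlation of 0.934 with its group, and omitting replicate C instead left 2012 calls. The count was 15 without exposed B, and 0, 6 and 16 without control A, B or C. The doses gave 0 calls against each other, with 2469 probes at an unadjusted p under 0.05, and 1395, 12 and 3 calls without 10 µg/mL replicate C, 10 µg/mL replicate B or 1 µg/mL replicate A.

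Males exposed to 1 µg/mL for 20 h had 63 probes higher and 235 lower. TC14908_613, under the floor on 2 of 3 exposed arrays, was at least 6.75-fold lower with median centring (adjusted p = 0.0032). The other probe of its prefix changed by -2.10 (adjusted p = 0.0025). The call of TC14908_613 was lost under 4 of 13 other settings and with 1 of 6 omissions, with adjusted p from 9.8e-04 to 0.25. Its log2 changes over these settings ran from -3.30 to -2.10, so the bound did not hold in all of them. TC15710_426 fell by 2.27 ± 0.46 (adjusted p = 0.0095) with -2.18 for the other probe (adjusted p = 0.0094), and lost its call under 2 of 13 settings and with 2 of 6 omissions. TC19414_361 was under the floor on 2 of 3 control arrays and in Cy3 on 5 of 6. With the control values raised to the floor it was 2.97-fold higher (adjusted p = 5.8e-04). That is no firm bound, because the dim Cy3 values stayed as measured. The other probe of its prefix did not pass (adjusted p = 0.60). The call of TC19414_361 was lost under 2 of 12 settings, with adjusted p from 3.7e-05 to 0.61 and log2 changes from 0.90 to 2.04. Rises were 21.1% of calls with median centring, 37.5% uncentred and 31.9% with centring on above-median probes. There were 195 calls with the reference batches as a block and 88 within batch 1. A fit on these 6 arrays alone called 0, and omission of control replicate A or exposed replicate A, B or C left 85, 137, 138 and 154.

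Females after 20 h showed a larger count at 10 than at 1 µg/mL. With 1 µg/mL 20 probes were higher and 88 lower, and with 10 µg/mL 670 were higher and 782 lower, 523 of them by at least 2-fold. A fit on only the groups compared called 0 and 448, and the replicate block left 30 at 1 µg/mL. TC16575_157 rose by 4.19 ± 0.38 at 10 µg/mL (adjusted p = 2.2e-08), as it had in 28 day worms, whereas the other probe of its prefix differed by 0.66 (adjusted p = 0.17). At the lower dose TC16575_157 differed by 1.00 ± 0.38 without passing (adjusted p = 0.28). TC11476_428, under the floor on all control arrays and in Cy3 on all 6, was at least 7.61-fold higher at 10 µg/mL (adjusted p = 1.2e-04), and the other probe of its prefix at least 3.26-fold. TC16051_215, under the floor on 2 of 3 exposed arrays, was at least 4.40-fold lower with median centring (adjusted p = 1.1e-05). Over 13 other settings its log2 change ran from -5.01 to -1.70, so the bound did not hold in all of them. Each of them kept the call. The other probe of its prefix, under the floor on 1 of 3, was at least 2.94-fold lower (adjusted p = 0.0059). In the 1 µg/mL comparison TC14701_110, under the floor on 1 of 3 exposed arrays, was at least 2.60-fold lower (adjusted p = 0.024), and TC13397_457 was higher by 1.81 ± 0.42 (adjusted p = 0.042). Neither call was firm. That of TC14701_110 was lost under 4 of 13 other settings, with adjusted p from 9.6e-04 to 0.42 and log2 changes from -4.01 to -1.26. The smallest of these changes was less than its 2.60-fold bound. The call of TC13397_457 was lost under 6 of 13, with adjusted p from 0.0043 to 0.36.

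The direct test between doses called 296 probes higher and 158 lower at 10 µg/mL, but 13 in a fit on only the groups compared. TC14322_1276 was higher by 3.72 ± 0.51 (adjusted p = 3.8e-05), and the other probe of its prefix by 1.95. Over 14 other settings its log2 change ran from 2.53 to 4.80, and 2 of them lost the call, with adjusted p up to 0.14. The rises were 65.2% of calls with median centring, 52.0% uncentred and 51.0% with centring on above-median probes. Omission of 1 µg/mL replicate A left 222 calls, and of 10 µg/mL replicate B or C 275 and 299.

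All 3 control arrays of the females and 1 of the exposed arrays at 10 µg/mL lay in reference batch 1, and the other exposed arrays at that dose in batch 3. With the batches as a block the count at 10 µg/mL was 544, and 459 of the 1452 probes were called in the same direction in both fits. Within batch 1, 219 probes were called. For 1 µg/mL there were 63 calls with the block and 10 within batch 1, and rises were 18.5% of calls with median centring, 64.2% uncentred and 60.6% with centring on above-median probes. That count came to 19, 10 and 29 without control A, B or C and to 33 and 14 without exposed A or C. Between doses there were 478 with the block, 125 within batch 1 and 56 within batch 3. Omission of any 1 array moved the count at 10 µg/mL by more than 1.5 times in 6 of 6 cases, to 716, 793 and 842 without control A, B or C, and to 2232, 644 and 645 without exposed A, B or C.

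The fold changes of females at the 2 doses correlated at 0.64, against 0.50 from simulated unchanged groups with shared controls, and the covariance was 0.069 against 0.025. The simulation drew each probe independently and held no batches, so a distance from 0.50 does not by itself show a shared response. All 3 female controls lay in reference batch 1, but 1 array at 1 µg/mL and 2 at 10 µg/mL lay in batch 3. After 1 h the doses correlated at 0.61 against 0.50 simulated in 28 day worms (covariance 0.056 against 0.025) and at 0.36 against 0.50 in males (covariance 0.027 against 0.025). The lists of females shared 6 rises and 41 falls, where independent lists would share 0.55 and 2.83, and part of the excess may come from the shared controls and the batches.

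Responses were then compared directly. The response to 1 µg/mL at 20 h differed between females and males in 49 probes, 32 with a higher and 17 with a lower log2 change in females, but in 5 with the reference batches as a block and in 0 within batch 1. It came to 10, 8, 11 and 23 without female control A or B or male control A or C, to 11 without exposed female C, and to 15, 28 and 32 without exposed male A, B or C. The response of 28 day worms differed between 20 and 1 h in 5624 probes at 1 µg/mL and 2915 at 10 µg/mL. These came to 5578 and 3509 with the block, and to 4492 and 2302 within batch 2. Rises made up 25.6% of the former and 23.7% of the latter with median centring, 41.3% and 46.3% uncentred, and 48.4% and 49.7% with centring on above-median probes, which moved the median of all probes by 0.22 and 0.20. In males, the response to 1 µg/mL differed between 20 and 1 h in 0 probes, with 1677 at an unadjusted p under 0.05, 34 with array weights and 39, 13 and 1 without the 1 h control C, the 1 h exposed C or the 20 h control A. The 1 h response differed between 28 day worms and males in 0 probes at 1 µg/mL, with 2342 at an unadjusted p under 0.05, 20 called within batch 3 and 22, 14 and 1 without male control C, male exposed C or 28 day control C. The 10 µg/mL response differed in 13, in 6 with the block, in 518 without male exposed C and in 0 without 28 day exposed C or male control B. Without 28 day control A, B or C it differed in 6, 29 and 2, without 28 day exposed B in 8, without male control C in 54, and without male exposed A or B in 4 and 36. The 28 day worms were mixed-sex pools, so age and sex composition differ together in this comparison with males.

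Unexposed females and males after 20 h differed in 9237 probes, 4568 higher and 4669 lower in females. TC8791_306 was higher in females by 9.63 ± 1.34 (adjusted p = 7.7e-07) and the other probe of its prefix by 9.58. TC8711_552 was higher by 9.25 ± 1.29 (adjusted p = 9.1e-07). TC9550_151 was at least 15.4-fold lower in females (adjusted p = 2.5e-13), and TC17408_473 was lower by a log2 change of -5.04 ± 0.24 (adjusted p = 8.4e-17), which quantile normalization made -8.27. The count was 8920 with the reference batches as a block and 8012 within batch 1.

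These sexes gave lists of 1301 female-biased and 1619 male-biased probes of above-median signal (called, with at least 2-fold difference), which were followed in worms not used to define them. In 28 day worms after 20 h, 339 female-biased probes were higher and 129 lower at 1 µg/mL, and 74 male-biased probes were higher and 740 lower. With centring on above-median probes these counts were 448, 78, 136 and 523. The median of female-biased minus that of male-biased probes, which no centring affects, averaged -0.02 ± 0.13 over the exposed arrays (SD, n = 6) and -0.65 ± 0.22 over the controls (SD, n = 3). All 6 exposed arrays lay above all 3 controls, with an exact two-sided permutation p of 0.012, the smallest that 84 splits allow, which was 0.11 after adjustment over 9 such tests. The difference was 0.63, and 0.60 within batch 2. In 28 day worms after 1 h it was -0.30 (exact permutation p = 0.11, adjusted 0.19), and in males after 1 h 0.09 (exact permutation p = 0.69).

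**Figure D4:**
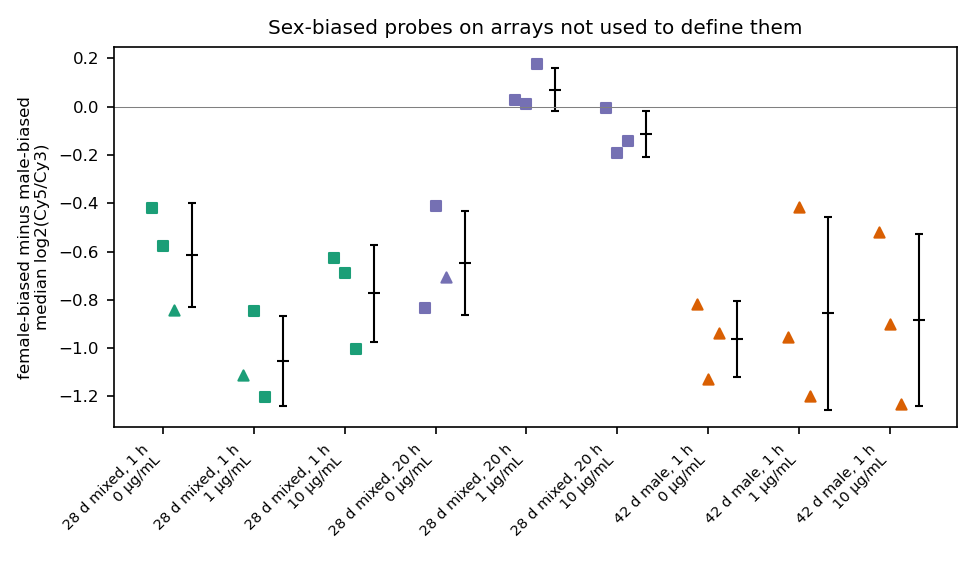
Median log2(Cy5/Cy3) of female-biased minus male-biased probes on each array (points; square for reference batch 2, triangle for 3) of the 28 day worms and of the 42 day males after 1 h, with mean ± SD (n = 3) as bars. The 6 exposed 28 day arrays after 20 h sit above their 3 controls.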

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

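The tests on sex-biased probes, on signal and on the bend of 1 array were chosen after their results were seen. The reference batches were found in the data, so the block and the counts within a batch were also chosen after seeing the data, as were removal of the trend with brightness and the regrouping of 1 set alone. For the counts without that trend, the count within batch 2, the correlation between batches, the mislabelled sample and the regrouping of arrays, limits were written before those values were seen but after the counts with the block. Responses differed between the sets compared in 4 tests, in 49 probes between females and males at 1 µg/mL, in 5624 and 2915 probes between 20 and 1 h in 28 day worms at 1 and 10 µg/mL, and in 13 probes between 28 day worms and males at 10 µg/mL after 1 h. Among 100 groupings of treatment labels within both sets, the real one included, only the real one gave as many as the 49, 5624 and 2915. For the 13, 4 gave as many, again with the real one included. The highest other groupings gave 48, 4392, 2556 and 78. Such groupings test for no response in either set, not for equal responses, so they leave open whether chance made these differences. With the real labels kept after 20 h, other labels of the 28 day 1 h arrays gave 995 to 4805 calls at 1 µg/mL and 628 to 2817 at 10 µg/mL, and 20 labellings are too few for a share under 0.05. With the real labels kept after 1 h, other labels of the 20 h arrays gave at most 995 and 813. With the female labels kept, 2 of 20 labellings of the males, the real one included, gave as many as the 49. The same held for 2 of 20 of the females with the male labels kept, and the highest other was 350 in both cases. Each 20 include the full exchange of exposed and control labels, which tests the sum of the responses and gives the same count in both cases. A count from that exchange is no measure of chance. For the 13, 6 of 20 gave as many with the 28 day labels kept, the real one included, up to 126. With the male labels kept only the real labelling did, the highest other giving 11. The 49 became 5 with the batches as a block, 0 within batch 1 and 0 in a fit on only the groups compared, and the 13 became 6 with the block and 0 in that fit.

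The wide change of 28 day worms after 20 h was set against technical explanations. Within reference batch 2, 4948 probes were called at 1 µg/mL and 3216 at 10 µg/mL, which argues against the batches as its whole source. Of the probes with a sex difference under 0.25, 26.1% were called at 1 µg/mL and 17.9% at 10 µg/mL under the lower of both centrings, which would argue against an altered sex ratio of the pools as the whole source only if 42 day sex differences held at 28 days, so the sex ratio stays open. Among the brightest 25% of probes 34.6% (2105 of 6083) were called at 1 µg/mL and 1523 of 6083 at 10 µg/mL, which argues against dim signal as the whole source. The exposed arrays also differed from their controls by brightness. In octiles 1 and 2 of signal (medians of 5.33 and 7.14 units) the median log ratio was -0.22 and -0.19 in the controls, 0.14 and 0.15 at 1 µg/mL and 0.18 and 0.18 at 10 µg/mL, and in octile 3 it was -0.02, -0.41 and -0.27. With the trend removed on each array there were 5234 and 3446 calls, which argues against this shift as the whole source of a count of that size. The calls were not all the same ones. At 1 µg/mL falls went from 4720 to 2612 and rises from 1597 to 2622, and at 10 µg/mL from 3450 to 1714 and from 960 to 1732. The cause of the shift itself stays open. The most female-biased probes (log2 above 4) were set against those between 1 and 2, with centring on above-median probes. At 1 µg/mL they changed by a median of 0.064 (quartiles -0.41 and 0.43) against 0.38, and at 10 µg/mL by 0.71 (0.22 and 1.24) against 0.29. RNA of mature females would raise the most biased probes more, which held in the medians at 10 but not at 1 µg/mL. At both doses their quartiles spanned the median of the less biased probes, so this cause stays open. A response to the drug is a further hypothesis.

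The change of females at 10 µg/mL fell from 1452 to 544 calls with the batches as a block. Of the 1452, 459 were called in the same direction with the block, and fold changes from the exposed arrays of batch 3 and from that of batch 1, each against different controls, correlated at 0.52 to 0.55 over 12166 probes, both of which argue against the batches as its whole source. Part of the count may still come from them, as 1 exposed array alone shares the controls' batch. Between doses, the split of the 6 arrays that followed the batches gave 1048 calls against the real 454. The batches were defined from Cy3, the denominator of the ratio. This split therefore cannot tell a difference between the samples from one in the reference channel.

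Replicate A of the males at 10 µg/mL after 1 h had octile medians of the log ratio that ranged over 0.78 in octiles 4 to 8 of signal, against 0.036 to 0.27 on the other arrays, while its Cy3 signal correlated at 0.997 with theirs. This bend with brightness is consistent with a fault of labelling or hybridisation of the Cy5 sample. Its mean Cy5 correlation was 0.934 with its own group and at most 0.935 with another, and the difference of 0.0015 cannot decide whether it belongs to another group. No biological explanation was tested.

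For comparisons of 3 against 3 arrays, 10 splits are too few for a share under 0.05. Every other split also mixes arrays of both groups, so a real change widens the spread within its groups and lowers its count. Low counts in other splits are then no measure of chance. The real count was the highest (1 of 10) for 28 day worms after 1 h (1 against 0 at 1 µg/mL and 57 against 0 at 10 µg/mL), after 20 h (6317 against 1 and 4410 against 1) and between doses after 20 h (2 against 0), for males after 20 h (298 against 8), for females (108 against 1 and 1452 against 1) and for unexposed females against males (9237 against 1). For males at 10 µg/mL after 1 h 3 splits, the real one included, gave as many as the real 2, the highest other giving 3. For females between doses 2 did, the real one included. With a real count of 0, all 10 splits did, the highest other giving 41 for males at 1 µg/mL, 3 between doses in 28 day worms and 2261 between doses in males, on a split that put replicates A and B at 10 µg/mL with B at 1 µg/mL. Among 100 groupings for the duration difference in males and the difference between 28 day mixed-sex worms and males at 1 µg/mL, both with 0 calls, all 100 gave as many, with highest others of 80 and 6.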

How the results depend on the processing

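Counts of called probes are given for the 20 comparisons with doses in µg/mL, and counts within 1.5 times the median-centred count of the fit on all arrays are left out. Age at 1 or 10 is short for the 1 h response of 28 day mixed-sex worms against that of 42 day males, where age and sex composition differ together. At 10 all exposed 28 day arrays lay in reference batch 2 and all male arrays in batch 3. The series matrix moved none. Without gene names the gene list tests (camera) and their alternatives were not run. The cause of each change was not tested, except that averaging probes leaves 12166 in place of all probes and fits on fewer arrays have fewer degrees of freedom. With the replicate block 15 of 20 counts stayed within that range, and the others were 0 for male 1 h at 10, 30 for female 20 h at 1, 1 for 28 d 20 h between doses, 18 for the sex difference and 4 for age at 10. Over all probes, dim ones included, same-letter arrays of a set deviated with correlations of -0.17 to 0.19. Such weak correlations show no clear pairing by letter but cannot exclude one. Fits on only the groups compared gave 0 for 28 d 1 h at 1, 1 for 28 d 1 h at 10, 0 for male 1 h at 10, 0 for male 20 h at 1, 0 for female 20 h at 1, 448 for female 20 h at 10, 0 for 28 d 20 h between doses, 13 for female 20 h between doses, 0 for the sex difference and 0 for age at 10. Quantile normalization gave 21 for 28 d 1 h at 1, 133 for 28 d 1 h at 10, 1 for male 1 h at 10, 96 for male 20 h at 1, 44 for female 20 h at 1, 740 for female 20 h at 10, 5 for 28 d 20 h between doses, 265 for female 20 h between doses, 20 for the sex difference, 4 for male duration and 2 for age at 10. Uncentred ratios gave 1 for male 1 h at 10, 67 for female 20 h at 1, 1 for male 1 h between doses and 76 for the sex difference. Without the dimmest 25% of probes the count was 1 for male 1 h at 10. Array weights gave 102 for 28 d 1 h at 1, 145 for 28 d 1 h at 10, 9477 for 28 d 20 h at 1, 8391 for 28 d 20 h at 10, 32 for male 1 h at 10, 2039 for male 20 h at 1, 544 for female 20 h at 1, 5253 for female 20 h at 10, 79 for 28 d 20 h between doses, 9 for male 1 h between doses, 2166 for female 20 h between doses, 817 for the sex difference, 5763 for 28 d duration at 10, 34 for male duration and 33 for age at 10. The mean of both probes of a prefix gave 7 for 28 d 1 h at 1, 3538 for 28 d 20 h at 1, 2502 for 28 d 20 h at 10, 1 for male 1 h at 10, 180 for male 20 h at 1, 901 for female 20 h at 10, 291 for female 20 h between doses, 3214 for 28 d duration at 1, 1705 for 28 d duration at 10, 4 for male duration and 5116 for females against males. 

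The following were chosen after seeing the data. The reference batches as a block gave 8 for 28 d 1 h at 1, 37 for 28 d 1 h at 10, 0 for male 1 h at 10, 195 for male 20 h at 1, 63 for female 20 h at 1, 544 for female 20 h at 10, 5 for the sex difference and 6 for age at 10. Within batch 1 the counts were 88 for male 20 h at 1, 10 for female 20 h at 1, 219 for female 20 h at 10, 125 for female 20 h between doses and 0 for the sex difference. Within batch 2 they were 6 for 28 d 1 h at 1, 22 for 28 d 1 h at 10 and 2 for 28 d 1 h between doses. Within batch 3 they were 38 for 28 d 1 h at 1, 0 for male 1 h at 10, 56 for female 20 h between doses and 20 for age at 1, where a lone array in a group is assumed to vary like the others. Centring on above-median probes gave 0 for male 1 h at 10, 71 for female 20 h at 1, 1 for male 1 h between doses, 79 for the sex difference, 1 for male duration and 24 for age at 10. Cy5 alone gave 4 for 28 d 1 h at 1, 4 for male 1 h at 1, 6 for male 1 h at 10, 109 for male 20 h at 1, 29 for female 20 h at 1, 1 for 28 d 1 h between doses, 44 for 28 d 20 h between doses, 1 for male 1 h between doses, 17 for the sex difference, 1 for male duration and 1 for age at 1. Removal of the trend with brightness gave 4 for 28 d 1 h at 1, 5 for male 1 h at 10, 104 for the sex difference, 5 for male duration and 23 for age at 10. Without the outlying male array the other comparisons gave 8 for 28 d 1 h at 1, 95 for 28 d 1 h at 10, 597 for male 20 h at 1, 345 for female 20 h at 1, 2263 for female 20 h at 10, 756 for female 20 h between doses, 196 for the sex difference and 6 for male duration. 

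Omission of each array in turn gave ranges of 0 to 17 for 28 d 1 h at 1, 21 to 89 for 28 d 1 h at 10, 0 to 22 for age at 1, 0 to 518 for age at 10, 0 to 8 for 28 d 1 h between doses, 2905 to 4361 for 28 d 20 h at 10, 0 to 11 for 28 d 20 h between doses, 0 to 15 for male 1 h at 1, 0 to 2012 for male 1 h at 10, 0 to 39 for male duration, 0 to 1395 for male 1 h between doses, 10 to 159 for female 20 h at 1, 644 to 2232 for female 20 h at 10, 8 to 73 for the sex difference, 85 to 216 for male 20 h at 1 and 222 to 629 for female 20 h between doses. It left 4 comparisons within 1.5 times, at 4145 to 5826 for 28 d duration at 1, 1968 to 3287 for 28 d duration at 10, 4414 to 6123 for 28 d 20 h at 1 and 7846 to 8555 for females against males. Of 37 changes listed by the rule for named genes, 20 lost their call under at least 1 other setting, in 71 of 474 cases, and 45 of 222 omissions of an array lost it; 0 reversed. Quantile normalization moved 11 of them by more than 1.5-fold, for instance TC14701_110 from -1.80 to -4.01, TC16051_215 from -2.47 to -5.01 and TC17408_473 from -5.04 to -8.27. Dim probes limit what could be called, since 11.1% to 30.8% of probes lay under the signal floor.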

Other observations

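Unexposed groups were also set against each other, in comparisons chosen after seeing the data. Unexposed 28 day worms and 42 day males after 1 h differed in 1088 probes, 537 higher and 551 lower at 28 days, and in 473 with the reference batches as a block and 274 within batch 3. The 28 day worms were mixed-sex pools, so age and sex composition differ together here. Rises were 49.4% of calls with median centring and 62.2% with centring on above-median probes. Unexposed males differed between 20 and 1 h in 333 probes, 194 higher and 139 lower at 20 h, but in 19 with the block and 27 within batch 3, with rises at 58.3% of calls against 44.0% uncentred. Unexposed 28 day worms differed between 20 and 1 h in 8 probes, 2 higher and 6 lower, in 12 with the block, in 0 within batch 2 and in 101 within batch 3, where 1 array stood on each side, with rises at 25% of calls against 12.5% uncentred. A fit on only the groups compared called 0 in each of these. Omission of 1 array gave 506 to 1276 for age, 22 to 846 for males and 1 to 36 for 28 day worms. Quantile normalization gave 2337, 966 and 96, array weights 2732, 3397 and 292, the mean of both probes of a prefix 594, 150 and 3, and omission of the outlying male array 1781, 988 and 42. The replicate block gave 903, 266 and 5. In 10 splits the highest other counts were 0, 2 and 2, too few splits for a share under 0.05. These other splits also mix arrays of both groups.

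A response common to 28 day worms and females at 10 µg/mL after 20 h was tested as a hypothesis after the overlap was seen. The lists shared 175 rises where independent lists would share 26.4, and 417 falls against 111, with 10 and 30 probes in opposite directions. Uncentred ratios gave 236 shared rises, 271 shared falls and 35 opposite, so the balance of rises and falls depended on centring. The fold changes correlated at 0.34 across 12166 probes, and at 0.50 with the batches as a block. Of 82 pairs of splits, the real one included, 19 gave a correlation as large in size, the highest other at 0.45. Other splits keep part of any real change in each set, so they cannot decide the hypothesis, which stays open. It may or may not be needed to explain the overlap. In 28 day worms at 1 µg/mL the fold changes after 1 and after 20 h, against separate controls, correlated at -0.53, with 1 of 82 pairs of splits as large and the highest other at 0.51. For 10 µg/mL the correlation was -0.35, with 8 of 82 as large and the highest other at 0.41, and for males 0.15, with 39 of 82 and 0.53. The same limit of the splits holds for these shares, which were not adjusted over the 7 pairs examined.

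A shift of exposed 28 day worms after 20 h towards the profile of females was likewise tested after it was seen. The exact permutation p was 0.012 and the adjusted value 0.11, so the hypothesis stays open. Omission of each array left the difference of the score between 0.54 and 0.75.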
